A study of Capra hircus with 9 samples.

How the data were processed

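Messenger RNA was profiled in uterine samples of Liaoning Cashmere goats (Capra hircus) at 3 time points, which the labels give as day 6, day 16 and day 19 peri-implantation, with 3 samples each. The labels do not say from which event the days are counted. The labels differ on the tissue: the tissue field gives uterus, the series title gives endometrial epithelium and the treatment protocol speaks of testis. The samples are called uterine here, and marker genes of each of these sources were measured. Nothing in the labels says that the 3 samples of a day came from separate animals, so p-values measure the spread between these samples, which may in part be technical.

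Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was purified on Dynabeads, cut into fragments with RNase III and ligated to adaptors with an Ion Torrent RNA-seq kit. Per the series design text, the libraries were sequenced on an Ion Proton. The authors deposited whole-number read counts per gene, without normalization, in a single table with 1 column per sample. The aligner, counting tool, genome build, annotation and use of strand are not given in the sources used here. Genes that share reads with close relatives, such as LGALS15 and LGALS16, the interferon-induced OAS and IFIT families, and the trophoblast Kunitz domain and pregnancy-associated glycoprotein families, are therefore uncertain one by one. The table held 25671 gene rows, of which 4121 had 0 counts in all 9 libraries; 20222 rows were of type mRNA and 4718 of type ncRNA. Gene symbols came from the table itself. For 464 of the 9672 rows named by a locus identifier, a symbol was taken from a reference gene table of assembly ARS1.2 by gene identifier; 23027 rows had their identifier in that table, and none of its coordinates were used.

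The counts summed to between 8712751 and 11074693 per library. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom between libraries of a group was 9.86, so all 9 were kept as separate samples. Ratios with 95% intervals are given for genes with 1 to 3 counts in a group, and a floor of 3 counts over the group was used where a group had 0 counts. These intervals and the floor cover counting error only.

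Genes were tested with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by the trimmed mean of M-values (TMM), low genes were removed with filterByExpr on the time point, and 16098 genes remained. A quasi-likelihood model with robust estimation was fitted to all 9 libraries with the time point as its only term, so that the 3 days share 1 estimate of the spread. The common biological coefficient of variation was 0.318. Day 16 was compared with day 6, day 19 with day 16 and day 19 with day 6, and an F test asked whether a gene differed among the 3 days. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Expression is given as TMM-normalized CPM, the count per gene scaled to a common library total, as mean ± SD over the 3 libraries of a day. Log2 fold changes of single genes from the fit to all 9 libraries are given with a standard error (SE) where they passed, and those from other fits without it. This SE was derived from the test, as the absolute change divided by the square root of the F statistic. It is approximate where a group has few counts.

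Before the data were examined, 34 gene lists were fixed: pathways of a ruminant uterus around implantation, signs of RNA handling and library composition, and markers of cell types the samples could hold. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison. No list call held with an estimated correlation between genes, and that adjusted p stands beside each call. Where members of a list are counted, the count is over all genes tested, and the count adjusted over the list alone follows it. The erythrocyte list had 0 of its 18 members tested and gives no result. The genes named were also set by a rule fixed beforehand. It took up to 8 genes per direction with the largest change among called genes, with an average log2 CPM of at least 3, no overlap between the groups and a true symbol. It added a panel of 20 uterine genes, of which 18 were tested (FOXA2 and MX2 are not analysed here, and 1 tested gene is not reported here), and the leading members of each list. Other genes are said to have been chosen after their values were seen.

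The calls were repeated with DESeq2 1.42.0, with limma voom and sample quality weights, with other scalings (RLE and upper quartile), without the low-count filter, with a stricter filter (at least 1 CPM in at least 6 libraries), without robust estimation, with only the libraries of the days compared, with the replicate number as a block, and without each library in turn. After the data were seen, 2 alternatives were added. The first represented day 19 by its replicate 1 alone, which is thereby assumed to vary like the libraries of the other days, so its p-values rest on their spread. The second used an index of long against short transcripts as a covariate. The test was checked on simulated counts drawn from the real means and library sizes, with 100 genes changed by each of 2 fold sizes. For day 16 against day 6 it recovered 12 of 100 genes changed 2-fold and 91 of 100 changed 8-fold, with 9 unchanged genes called among the 15854 genes of that simulation. DESeq2 recovered 32 and 94 on its simulation of the same comparison, and called 50 unchanged genes among 16098. For day 19 against day 16 the main test recovered 8 and 86 with 1 unchanged gene called, and for day 19 against day 6 it recovered 6 and 86 with 5 unchanged genes called.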

Results

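Polyadenylated RNA from the uterus of Liaoning Cashmere goats, a fibre breed, was counted per gene at days 6, 16 and 19, with 3 libraries per day. The series title places these days around implantation, when the ruminant conceptus elongates and attaches to the uterine lining. The libraries held 9551686 to 9798910 counts at day 6, 8712751 to 10330038 at day 16 and 10611186 to 11074693 at day 19, and 18530 to 19243 genes were detected per library. Collagens and smooth muscle genes were the most abundant: the highest means over all 9 libraries were those of COL3A1 at 7213 CPM, COL1A2 at 6552, FLNA at 6440 and ACTA2 at 6232. The epithelial adhesion gene EPCAM stood at 197 ± 10.4 CPM at day 6, 330 ± 50.7 at day 16 and 320 ± 107 at day 19. Of the 37 testis germ cell genes on the list, 5 passed the low-count filter.

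The first principal component of the 500 most variable genes held 69.7% of their variance and separated day 6 from the later days, and the second held 13.1%. The day 19 libraries were less alike than those of the other days. Over genes, Spearman's rho of day 19 replicate 1 was 0.952 with replicate 2 and 0.953 with replicate 3, against 0.968 to 0.974 with the day 16 libraries; genes are not independent replicates. Replicates 2 and 3 correlated at 0.980. Ribosomal protein genes held 2.62% of the counts in day 19 replicate 1, 7.04% in replicate 2 and 6.03% in replicate 3, and 3.93% to 4.62% in the day 6 and day 16 libraries. The mitochondrial genome held 3.06% ± 0.187 of the counts at day 6, 2.02% ± 0.085 at day 16 and 1.17% ± 0.473 at day 19 (SD, n = 3 each). The day 6 libraries were uneven too. Of their medians of log2 CPM, centred per gene, that of the smooth muscle list was -1.27 in replicate 1 and 0.50 and 0.23 in replicates 2 and 3, and that of the macrophage list was 0.06, -1.03 and -0.74.

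**Figure D1:**
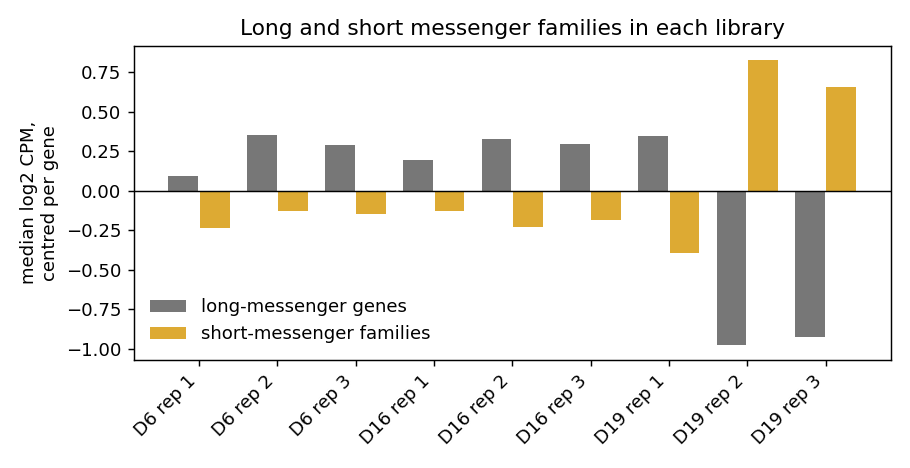
Median log2 CPM, centred per gene (vertical axis), of 75 genes with long messengers (grey bars) and 223 genes of 6 families with short messengers (yellow bars) in each of the 9 libraries (horizontal axis). The short families stand at 0.83 and 0.66 in day 19 replicates 2 and 3 and between -0.40 and -0.13 in the other 7 libraries.

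The comparison of day 16 with day 6 asked which genes differed between the early and the later uterus. Interferon-stimulated genes, which antiviral cytokines induce, were far higher at day 16. ISG15, a ubiquitin-like protein that is attached to other proteins, rose from 4.65 ± 1.75 to 964 ± 526 CPM, or 207-fold (log2 fold change 7.69, SE 0.56). MX1, an antiviral GTPase, rose 39.5-fold to 1438 ± 661 CPM. GRP, which encodes gastrin-releasing peptide, went from 5.96 ± 3.10 to 1589 ± 705 CPM, 266-fold. CCNB1, the cyclin of entry into mitosis, fell by 4.34 on the log2 scale (SE 0.36), from 62.0 ± 12.3 to 3.04 ± 0.863 CPM (SD, n = 3 each). The adjusted p-values of these 4 genes lay between 0.00015 and 0.000211 (edgeR quasi-likelihood, Benjamini-Hochberg).

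Of 16098 genes tested, 825 were higher and 602 lower at day 16, and 1178 of these 1427 changed by at least 1 on the log2 scale. DESeq2 called 2238. The count moved when 1 library was left out. It was 830, 795 and 664 without day 6 replicates 1, 2 and 3, and 773 and 762 without day 16 replicates 1 and 2. A smaller group gives less power, so these falls need not rest on particular libraries. The count was 3345 without day 19 replicate 1. That library enters this comparison through the shared estimate of the spread, the filter and the scaling. Which of these moved the count was not tested on its own. With the filter and scaling unchanged, the count was 3391 with the long-minus-short index as a covariate and 3811 with voom. A count of that size therefore did not need another filter or scaling, but both fits also changed the model.

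The interferon-stimulated list had 46 tested members, of which 41 rose at day 16 over all genes and 46 when adjusted over the list alone. Its median log2 fold change was 3.45 (camera, adjusted p = 1.72e-47; adjusted p = 0.194 with an estimated correlation). Besides ISG15, RSAD2 rose 166-fold (101-fold without day 16 replicate 2), the exonuclease gene ISG20 rose 179-fold (278-fold without day 6 replicate 2) and the chemokine CXCL10 rose 21.6-fold. In the class I antigen presentation list 8 of 16 members rose, 10 when adjusted over the list alone (camera, adjusted p = 3.01e-07; adjusted p = 0.261 with an estimated correlation). TAP1, a peptide transporter, rose 5.02-fold and PSMB9, an immunoproteasome subunit, rose 4.08-fold. Of 20 complement genes 7 rose, also 7 when adjusted over the list alone (camera, adjusted p = 2.81e-06; adjusted p = 0.316 with an estimated correlation), among them CFB 9.80-fold and C2 9.0-fold.

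Genes of uterine secretion made up the next group. Of 30 tested secreted and histotroph genes, 8 rose and 1 fell, or 10 and 1 when adjusted over the list alone (camera, adjusted p = 2.48e-06; adjusted p = 0.194 with an estimated correlation). LGALS15, a galectin of the ruminant uterine lumen, rose from 0.279 ± 0.482 to 1182 ± 162 CPM, with its 9 day 6 counts all in replicate 1, and its relative LGALS16 reached 625 ± 162 CPM. LGALS16 had 2 counts over the day 6 libraries, which gives a ratio of 9520 with a counting interval of 2630 to 78600. Both counts lie in replicate 1, and without it LGALS16 was at least 4120-fold higher; without replicate 3 the ratio was 6340. Reads of this pair could be split by the counting. IGFBP1, which binds insulin-like growth factors, had 1 count at day 6 and 116 ± 72.8 CPM at day 16, a ratio of 3630 (652 to 144000; at least 787-fold higher without day 6 replicate 1). The chemokine CXCL14 rose 101-fold. CLEC4F, a C-type lectin, rose 316-fold (548-fold without day 6 replicate 1). IL1R2, the decoy receptor of interleukin 1, rose 1210-fold (2570-fold without day 6 replicate 1 and 751-fold without day 16 replicate 1). The serpin SERPINA14, known as uterine milk protein, stood at 101 ± 85.4 and 449 ± 179 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.114; 0.0489 without day 19 replicate 1; 0.0124 in DESeq2). CTSL and SPP1 passed in neither tool, with edgeR adjusted p of 0.303 and 0.518.

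Of 9 glucose transporters 4 rose and 1 fell at day 16, with the same counts when adjusted over the list alone (camera, adjusted p = 0.0108; adjusted p = 0.194 with an estimated correlation). The sodium-glucose cotransporter SLC5A1 had 2 counts at day 6 and 58.5 ± 27.3 CPM at day 16, a ratio of 903 (250 to 7470), and SLC2A1 rose 6.43-fold. Of 24 amino acid transporters 6 rose, and 6 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 0.0556; 0.0476 and 0.0211 without day 6 replicates 1 and 2, 0.0439 and 0.0432 without day 16 replicates 2 and 3). SLC7A9, with 4 counts over the day 6 libraries, rose 1290-fold and SLC36A2 rose 18.2-fold. Of 29 integrin and adhesion genes 7 rose and 1 fell, or 11 and 2 when adjusted over the list alone (camera, adjusted p = 0.000877; adjusted p = 0.407 with an estimated correlation). Here the mucins MUC16 and MUC1, glycoproteins of the apical cell surface, rose 92.0-fold (252-fold without day 6 replicate 1) and 10.7-fold, and the integrin subunit ITGB6 rose 41.2-fold. The epithelium list had 6 higher and 1 lower of 25, or 10 and 3 when adjusted over the list alone (camera, adjusted p = 0.0367; adjusted p = 0.587 with an estimated correlation), and MAL2 rose 11.8-fold. The call of this list was lost without day 6 replicate 2 (0.0508) or 3 (0.0581), day 16 replicate 3 (0.0664) or day 19 replicate 1 (0.0921). Of 32 junction genes 4 rose and 2 fell, or 8 and 3 when adjusted over the list alone (camera, adjusted p = 0.144), and CGN rose 3.68-fold; the deposited table describes the CGN row as conglutinin in 1 column and as the tight junction protein cingulin in another.

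In the cell cycle list 9 of 35 fell at day 16, 20 when adjusted over the list alone (camera, adjusted p = 2.93e-08; adjusted p = 0.407 with an estimated correlation), including BIRC5 with a log2 fold change of -4.08 (SE 0.69). Of 22 cholesterol genes 4 fell, also 4 when adjusted over the list alone (camera, adjusted p = 0.000367; adjusted p = 0.218 with an estimated correlation); SQLE and LSS, enzymes of sterol synthesis, changed by -1.45 (SE 0.21) and -1.37 (SE 0.20). Of 36 matrix genes 3 fell, also 3 when adjusted over the list alone (camera, adjusted p = 0.0341; adjusted p = 0.587 with an estimated correlation). That call was lost without day 6 replicate 2 (0.0508) or 3 (0.058) or day 16 replicate 3 (0.134). Single genes with large decreases were PDZK1, a scaffold of membrane transporters, at -6.31 (SE 0.51; -6.93 without day 16 replicate 1), the basal keratin KRT5 at -6.31 (SE 0.76; -5.56 without day 6 replicate 1) and PSAT1, an enzyme of serine synthesis, at -4.59 (SE 0.37). The urea transporter SLC14A1 changed by -7.74 (SE 1.10), with 2050 of its 2636 day 6 counts in replicate 1; the change was -6.25 without that library and -8.36 without day 16 replicate 2. PSAT1 went from 464 ± 18.3 to 19.3 ± 5.77 CPM (SD, n = 3 each).

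Among receptors and developmental regulators, the oestrogen receptor ESR1 fell from 752 ± 47.4 to 318 ± 73.8 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0244). That p was 0.0827, 0.0729 and 0.0756 without day 6 replicates 1, 2 and 3, and 0.105 and 0.101 without day 16 replicates 1 and 3. The progesterone receptor PGR and the oxytocin receptor OXTR passed in neither edgeR nor DESeq2, with edgeR adjusted p of 0.595 and 0.901. HSD11B1, which regenerates active glucocorticoid, rose 102-fold (160-fold without day 6 replicate 1) and was the member of the steroid and oxytocin receptor list to rise; 2 of its 20 members fell, and 1 rose and 3 fell when adjusted over the list alone (camera, adjusted p = 0.347). Of 21 prostaglandin genes 4 rose and 1 fell, or 6 and 2 when adjusted over the list alone (camera, adjusted p = 0.206). PTGS2, the inducible cyclooxygenase, rose 32.2-fold, and AKR1B1 fell by 2.26 on the log2 scale (SE 0.30). Of 29 implantation regulators 5 rose and 4 fell, or 7 and 5 when adjusted over the list alone (camera, adjusted p = 0.945; its mean and median log2 fold change were -0.086 and 0.174). The hedgehog ligand IHH and its receptor PTCH1 fell by 4.12 (SE 0.38) and 1.95 (SE 0.24) on the log2 scale. Of 35 Wnt genes 3 rose and 6 fell, also 3 and 6 when adjusted over the list alone (camera, adjusted p = 0.0602; 0.0476 and 0.0353 without day 6 replicates 1 and 2). WNT7A, a ligand of the uterine epithelium, changed by -4.90 (SE 0.94; -4.23 without day 6 replicate 1 and -4.27 without day 16 replicate 3), WNT2B by -1.93 (SE 0.22). The change of WNT7A rests on 4 counts over the day 16 libraries.

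Of 25 cytokines and NF-kB targets 8 rose at day 16, 14 when adjusted over the list alone (camera, adjusted p = 8.52e-10; adjusted p = 0.194 with an estimated correlation), and the monocyte attractant CCL2 rose 9.50-fold. Immediate early and stress genes, which also respond to tissue handling, rose for 11 of 21 members, 17 when adjusted over the list alone (camera, adjusted p = 4.93e-12; adjusted p = 0.194 with an estimated correlation), with ATF3 at 31.4-fold. Of 29 angiogenesis and hypoxia genes 5 rose, also 5 when adjusted over the list alone (camera, adjusted p = 0.00763; adjusted p = 0.467 with an estimated correlation), with EPAS1 at 5.14-fold. Of 11 B and plasma cell genes 1 rose, 6 when adjusted over the list alone (camera, adjusted p = 0.0106; adjusted p = 0.467 with an estimated correlation), and this call was lost without day 16 replicate 1 at 0.101. Of 30 endoplasmic reticulum stress genes 4 rose, also 4 when adjusted over the list alone (camera, adjusted p = 0.416; its median was -0.01 and its mean 0.10). Of 10 gland genes 3 rose and 2 fell, or 4 and 4 when adjusted over the list alone (camera, adjusted p = 0.455). The gland markers PIGR and PAX8 rose 99.6-fold (65.3-fold without day 16 replicate 2) and 2.93-fold.

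Genes of the mitochondrial genome had a median log2 fold change of -0.54 (camera, adjusted p = 0.00859; adjusted p = 0.587 with an estimated correlation). None of the 13 passed in edgeR, also 0 when adjusted over the list alone; 3 had an unadjusted p under 0.05 and DESeq2 called 1. Of the cell type lists, ciliated epithelium had 1 lower of 25, stromal fibroblast 1 lower of 26 and macrophage 1 higher of 19, or 1, 1 and 4 when adjusted over the list alone (camera, adjusted p = 0.0635, 0.0996 and 0.0536). The T and NK lymphocyte list had 0 of 25 in edgeR, 3 when adjusted over the list alone, 4 at unadjusted p under 0.05 and 4 by DESeq2 (camera, adjusted p = 0.0716). Endothelium had 0 of 21 in edgeR and 0 when adjusted over the list alone, 2 higher and 1 lower unadjusted, and 1 by DESeq2 (camera, adjusted p = 0.698). Smooth muscle with 21 members, ribosomal proteins with 52 and trophoblast genes with 8 of 35 listed had 0 in edgeR, 0 when adjusted over the list alone, 0 unadjusted and 0 by DESeq2 (camera, adjusted p = 0.851, 0.682 and 0.726). A trophoblast Kunitz domain row outside those 8 did pass in edgeR, as given under the other observations. Class II antigen presentation with 5 and testis germ cell with 5 had 0 in edgeR, 0 when adjusted over the list alone, 1 each unadjusted and 0 by DESeq2 (camera, adjusted p = 0.0954 and 0.799). For smooth muscle and testis germ cell the medians were -0.11 and -0.28, while camera's direction was up. Without day 6 replicate 1 the smooth muscle list turned downward and passed at 0.00203, and the macrophage, lymphocyte and class II lists passed at 0.000457, 0.0103 and 0.013. Ciliated epithelium passed without day 6 replicates 2 (0.0413) and 3 (0.000311) and day 16 replicate 3 (0.000957). Macrophage passed without day 16 replicates 1 (0.0432) and 3 (0.0242), and lymphocyte without day 16 replicates 2 (0.0198) and 3 (0.0128). Without the low-count filter ciliated epithelium, macrophage and lymphocyte passed at 0.0255, 0.0255 and 0.0342.

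**Figure D2:**
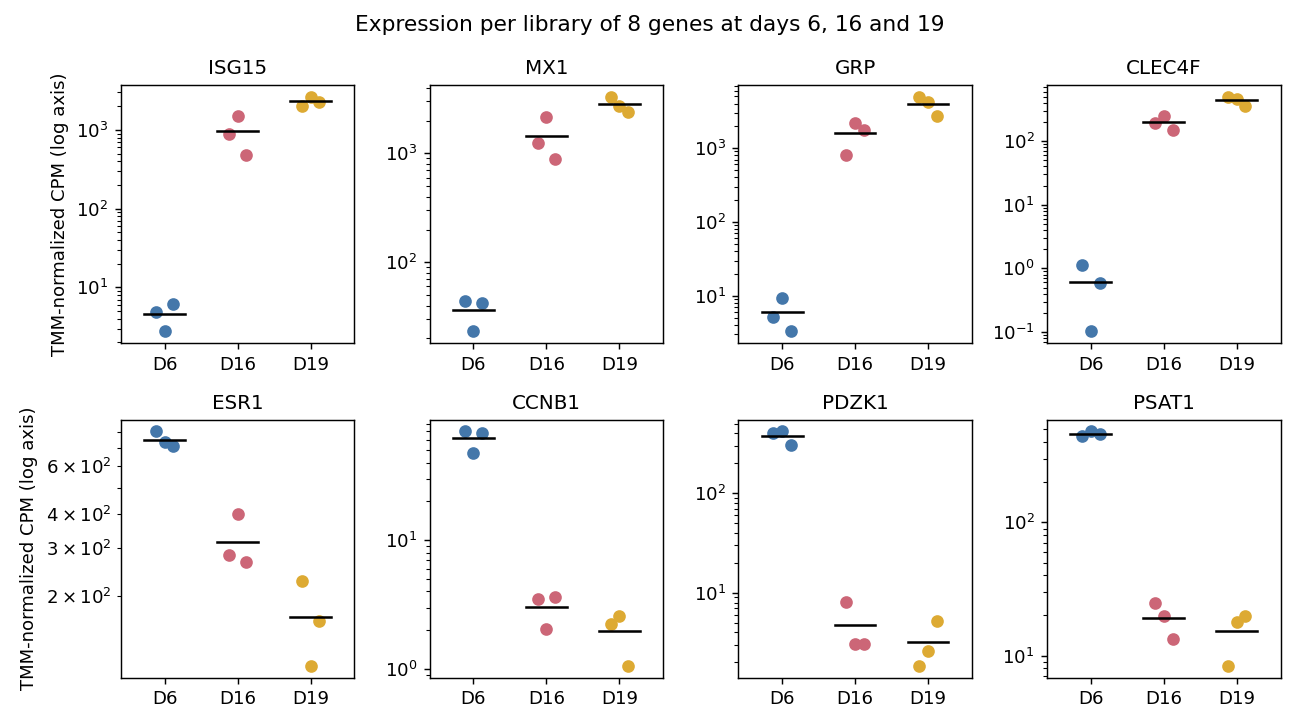
TMM-normalized CPM (log axis) of 8 genes at days 6, 16 and 19 (horizontal axis); each point is 1 of 3 libraries per day and each black line the mean of a day. ISG15 had means of 4.65, 964 and 2307 CPM and ESR1 had means of 752, 318 and 167 CPM.

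The comparison of day 19 with day 16 asked what changed further over the later days, and it rests on day 19 libraries that differ among themselves. CST6, a secreted inhibitor of cathepsins, rose from 21.3 ± 13.8 to 167 ± 70.3 CPM, 7.88-fold. INHBA, which encodes an activin subunit, rose 4.27-fold to 232 ± 57.0 CPM. The integrin subunit ITGB3 fell by 2.94 on the log2 scale (SE 0.52; a log2 fold change of -3.72 without day 19 replicate 1), from 70.4 ± 25.2 to 9.16 ± 6.70 CPM, and SLC7A9, a transporter of cystine and basic amino acids, fell by 2.75 (SE 0.49), from 184 ± 77.1 to 27.3 ± 14.8 CPM (SD, n = 3 each). Their adjusted p-values lay between 0.0408 and 0.0492 (edgeR quasi-likelihood, Benjamini-Hochberg).

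In all, 83 genes were higher and 110 lower at day 19, and 171 of these 193 changed by at least 1 on the log2 scale; 3946 genes had an unadjusted p under 0.05 and DESeq2 called 1681. Without day 19 replicate 1 the count was 7331. It was 6 and 5 without day 19 replicates 2 and 3, 16, 6 and 0 without day 6 replicates 1, 2 and 3, and 0, 7 and 0 without day 16 replicates 1, 2 and 3. With only the 6 libraries of these days edgeR called 0 genes (2726 unadjusted). Each of the 25 called genes named for this comparison lost its call without at least 1 library, and with day 19 represented by its replicate 1 alone 180 genes were called, of which 37 were among the 193.

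Further called genes were PNMT at 7.80-fold, the enolase ENO2 at 3.86-fold and the G protein subunit GNG11 at 3.94-fold higher. The log2 fold changes of the lower genes were -3.25 (SE 0.42) for OVCH1, -3.02 (SE 0.36) for the kinesin KIF1A, -2.87 (SE 0.57; -3.56 without day 19 replicate 3) for the fucosyltransferase FUT1, -2.55 (SE 0.43; -3.19 without day 19 replicate 2) for the aminotransferase BCAT1 and -1.80 (SE 0.28) for the glutamate transporter SLC1A1. Over the fits that each left out a library, the highest adjusted p of these 8 genes lay between 0.0974 and 0.177. GNG11 kept its call without any 1 of the day 19 libraries. Among implantation regulators the transcription factors KLF5 and HOXA11 changed by -1.35 (SE 0.17) and 1.39 (SE 0.25). The list had 1 higher and 1 lower of 29, or 3 and 4 when adjusted over the list alone (camera, adjusted p = 0.136).

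No member of the interferon-stimulated list passed in edgeR, although the list as a group lay higher at day 19 with a median log2 fold change of 0.35 (camera, adjusted p = 0.00372; adjusted p = 0.646 with an estimated correlation). Of its 46 members 4 rose when adjusted over the list alone, 14 had an unadjusted p under 0.05 and DESeq2 called 8. ISG15 stood at 964 ± 526 and 2307 ± 328 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.126; 0.0355 without day 19 replicate 1; 0.0308 in DESeq2) and MX1 at 1438 ± 661 and 2824 ± 461 CPM (0.156). The changes of RSAD2 and CXCL10 were -0.70 (SE 0.60) and 0.56 (SE 0.44), and neither passed in edgeR or DESeq2. RSAD2 turned to 0.02 without day 16 replicate 2. The call of the list was lost without day 19 replicate 1 (0.614), and without day 16 replicate 3 (0.119). Class I antigen presentation had 0 of 16 in edgeR, 3 when adjusted over the list alone, 7 unadjusted and 4 by DESeq2 (camera, adjusted p = 0.0266; adjusted p = 0.645 with an estimated correlation). Complement had 0 of 20 in edgeR, 1 when adjusted over the list alone, 6 higher and 1 lower unadjusted, and 4 higher and 1 lower by DESeq2 (camera, adjusted p = 0.0266; adjusted p = 0.645 with an estimated correlation). These calls were lost without day 16 replicate 3 (0.119 each) and without day 19 replicate 1 (0.355 each).

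Of 32 junction genes 2 fell, and 2 rose and 6 fell when adjusted over the list alone (camera, adjusted p = 0.0117; adjusted p = 0.645 with an estimated correlation). OCLN, a tight junction gene, and CGN, with the 2 descriptions noted above, changed by -1.15 (SE 0.21) and -0.98 (SE 0.19), and the call of the list was lost without day 19 replicate 1 (0.154) and with that library alone for day 19 (0.0805). The cell cycle list had 0 of 35 in edgeR, 0 when adjusted over the list alone, 12 higher and 1 lower unadjusted, and 6 by DESeq2, with a median of 0.51 (camera, adjusted p = 0.00372; adjusted p = 0.645 with an estimated correlation); its call was lost without day 19 replicate 1 (0.154). Of 22 cholesterol genes 1 rose, 8 when adjusted over the list alone (camera, adjusted p = 0.0266; adjusted p = 0.645 with an estimated correlation). HMGCS1, an early enzyme of that pathway, rose 1.87-fold, and the list's call was lost without day 19 replicate 1 (0.365) or day 16 replicate 3 (0.0713). The macrophage list had 0 of 19 in edgeR, 1 higher and 1 lower when adjusted over the list alone, 7 higher and 1 lower unadjusted, and 3 higher and 1 lower by DESeq2 (camera, adjusted p = 0.00755; adjusted p = 0.645 with an estimated correlation). That call was lost without day 19 replicate 1 (0.168).

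Of 13 mitochondrial genes 2 fell, 3 when adjusted over the list alone (camera, adjusted p = 0.0064; adjusted p = 0.645 with an estimated correlation). ND4L and ND5, subunits of respiratory complex I, changed by -2.28 (SE 0.20) and -1.45 (SE 0.24), and the call of the list was lost without day 19 replicate 1 (0.387). The 52 ribosomal protein genes had a median of 0.46, 0 called in edgeR, 0 when adjusted over the list alone, 5 unadjusted and 1 by DESeq2 (camera, adjusted p = 0.0064; adjusted p = 0.754 with an estimated correlation). This call was lost without day 19 replicate 2 (0.387) or 3 (0.167), and turned downward with day 19 represented by its replicate 1 alone (2.58e-15).

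The other lists were not called between these days. Without day 19 replicate 2, matrix, angiogenesis, epithelium, stromal fibroblast, smooth muscle and endothelium passed at 0.019, 0.019, 0.0165, 0.019, 0.0165 and 0.0394. Smooth muscle also passed without day 6 replicate 1 (0.0224), secreted genes without day 19 replicate 3 (0.0211), B cells without day 16 replicate 3 (0.0182) and endoplasmic reticulum stress without day 16 replicate 1 (0.0474). Angiogenesis also passed without the low-count filter (0.0476). With day 19 represented by its replicate 1 alone, matrix, cytokines and NF-kB targets, and epithelium passed at 0.00299, 0.00415 and 0.000112. ESR1 stood at 318 ± 73.8 and 167 ± 58.5 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.107; 0.00226 without day 19 replicate 1). IGFBP1 stood at 116 ± 72.8 and 18.7 ± 14.1 CPM (0.0753), and HSD11B1 at 73.2 ± 39.8 and 10.4 ± 3.83 CPM (0.0612; 0.0169 without day 19 replicate 1). SLC5A1 stood at 58.5 ± 27.3 and 14.1 ± 8.28 CPM (0.0774; 0.00651 without it), SPP1, a secreted ligand of integrins, at 15.4 ± 1.10 and 101 ± 84.1 CPM (0.0771; 0.0388 without it) and PTGS2 at 105 ± 52.3 and 35.1 ± 31.3 CPM (0.199; 0.0239 without it). SERPINA14 reached 1955 ± 1717 CPM at day 19 (0.134), and LGALS15 stood at 1182 ± 162 and 2028 ± 1608 CPM (0.459). PGR, OXTR, CTSL, MUC1 and WNT7A had adjusted p-values of 0.574, 0.583, 0.993, 0.502 and 0.175 in edgeR. Of the genes in this paragraph that did not pass in edgeR, DESeq2 called ESR1 (0.0244), IGFBP1 (0.00246), HSD11B1 (0.000257), SLC5A1 (0.00565), SPP1 (0.000945) and SERPINA14 (0.0202). Single called members of other lists were TIMP1 at 2.28-fold and COL18A1 at 2.40-fold higher in the matrix list, WNT11 at 3.42-fold higher and the stem cell receptor LGR5 at -2.25 (SE 0.39; -2.85 without day 19 replicate 3) in the Wnt list, FLT1 at -1.34 (SE 0.27) among angiogenesis genes and the stress factor DDIT3 at 2.38-fold higher.

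The comparison of day 19 with day 6 spans the whole series. Interferon-stimulated genes again had the highest median change of the lists tested: ISG15 rose from 4.65 ± 1.75 to 2307 ± 328 CPM, 494-fold, and IFI6 rose 133-fold to 6350 ± 1346 CPM. GRP rose 663-fold to 3953 ± 1155 CPM, and CLEC4F rose 706-fold (1210-fold without day 6 replicate 1) to 441 ± 72.7 CPM. ESR1 fell from 752 ± 47.4 to 167 ± 58.5 CPM, a log2 fold change of -2.17 (SE 0.29), and CCNB1 by -4.97 (SE 0.37), from 62.0 ± 12.3 to 1.96 ± 0.804 CPM (SD, n = 3 each). Their adjusted p-values lay between 6.53e-05 and 0.0011 (edgeR quasi-likelihood, Benjamini-Hochberg).

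At day 19, 2049 genes were higher and 1635 lower than at day 6, and 2693 of these 3684 changed by at least 1 on the log2 scale. The F test called 3156 genes over the 3 days. Higher calls were 55.6% of the total, and 49.0% with upper quartile scaling. The count was 2211, 2111 and 1928 without day 6 replicates 1, 2 and 3, 2355 without day 19 replicate 2 and 8891 without day 19 replicate 1. The F test gave 1720, 1659 and 1416 without day 6 replicates 1, 2 and 3, 1989 and 2083 without day 19 replicates 2 and 3, and 9703 without day 19 replicate 1.

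In the interferon-stimulated list 45 of 46 rose, also 45 when adjusted over the list alone, with a median of 4.02 (camera, adjusted p = 3.78e-32; adjusted p = 0.375 with an estimated correlation). MX1 rose 77.5-fold, RSAD2 102-fold (57.6-fold without day 19 replicate 1), OAS2 131-fold, ISG20 313-fold (487-fold without day 6 replicate 2) and CXCL10 31.9-fold; reads of OAS2 could be shared with other OAS genes. Class I antigen presentation had 11 of 16 higher, 12 when adjusted over the list alone (camera, adjusted p = 9.62e-07; adjusted p = 0.375 with an estimated correlation), with TAP1 at 6.92-fold and PSMB9 at 7.26-fold. Class II antigen presentation had 2 of 5 higher, also 2 when adjusted over the list alone (camera, adjusted p = 0.0461; adjusted p = 0.738 with an estimated correlation). That call was lost without day 6 replicate 2 (0.0877) or 3 (0.0691), day 16 replicate 2 (0.0543) or day 19 replicate 1 (0.0675), 2 (0.0889) or 3 (0.0533), and with day 19 represented by its replicate 1 alone (0.371). Of 20 complement genes 14 rose, 15 when adjusted over the list alone (camera, adjusted p = 1.82e-06; adjusted p = 0.375 with an estimated correlation): C2 rose 15.0-fold, CFB 7.09-fold and the inhibitor SERPING1 7.76-fold. Of 19 macrophage genes 9 rose and 1 fell, or 10 and 1 when adjusted over the list alone (camera, adjusted p = 0.00193; adjusted p = 0.701 with an estimated correlation), and AIF1 and CD14 rose 6.53-fold and 4.11-fold.

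Of 30 secreted and histotroph genes 14 rose and 1 fell, or 17 and 1 when adjusted over the list alone (camera, adjusted p = 9.62e-07; adjusted p = 0.375 with an estimated correlation). SERPINA14 rose 19.4-fold (37.7-fold without day 6 replicate 2 and 9.72-fold without day 19 replicate 1). LGALS15 reached 2028 ± 1608 CPM, with 38618 of its 60380 day 19 counts in replicate 2. LGALS16 had a ratio of 9420 (2610 to 77800) over 2 counts at day 6, and IGFBP1 a ratio of 582 (104 to 23000) over 1 count. Day 19 replicate 2 held 11232 of 18250 counts of LGALS16 and 341 of 563 of IGFBP1, and without it the ratios were 5460 and 346. The day 6 counts of both genes lie in replicate 1, and without it they were at least 4080-fold and 126-fold higher; without day 6 replicate 3 the ratio of IGFBP1 was 387. SPINK7, a serine protease inhibitor with 0 counts at day 6, was at least 369-fold higher, with 933 of its 1072 day 19 counts in replicate 2. That bound was 72.1-fold without day 19 replicate 2, 557-fold without day 19 replicate 1 and 240-fold without day 6 replicate 1. Of 25 cytokines and NF-kB targets 14 rose, 16 when adjusted over the list alone (camera, adjusted p = 4.38e-07; adjusted p = 0.375 with an estimated correlation), and CCL2 rose 15.5-fold. Of 21 immediate early and stress genes 13 rose, 15 when adjusted over the list alone (camera, adjusted p = 4.09e-07; adjusted p = 0.375 with an estimated correlation), with ATF3 at 22.3-fold and GADD45B at 6.75-fold. The stress factors DDIT3 and ATF4 rose 4.98-fold and 3.39-fold in the endoplasmic reticulum stress list, where 7 of 30 rose and 2 fell, or 8 and 2 when adjusted over the list alone (camera, adjusted p = 0.160).

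In the Wnt list 11 of 35 fell and 3 rose at day 19, the same counts when adjusted over the list alone (camera, adjusted p = 0.0173; adjusted p = 0.562 with an estimated correlation). The inhibitor WIF1 changed by -3.86 (SE 0.61), LGR5 by -3.33 (SE 0.40), the pathway target AXIN2 by -2.67 (SE 0.58; -3.86 without day 19 replicate 1) and WNT7A by -2.42 (SE 0.75; -1.77 without day 6 replicate 1 and -3.41 without day 19 replicate 1). Without day 19 replicate 3 WIF1 and LGR5 changed by -4.57 and -3.93. The call of the list was lost with day 19 represented by its replicate 1 alone (0.453). WNT7A (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0447) lost its call without day 6 replicate 1 (0.172), 2 (0.0605) or 3 (0.0809), day 16 replicate 1 (0.0651) or 2 (0.0637), and day 19 replicate 2 (0.134) or 3 (0.127). IHH and PTCH1 changed by -4.37 (SE 0.38) and -2.37 (SE 0.24). PTGS2 rose 10.8-fold (adjusted p = 0.0134 in edgeR; 0.0562 and 0.0583 without day 6 replicates 2 and 3; 5.59-fold without day 19 replicate 1), and AKR1B1 changed by -1.74 (SE 0.30). HSD11B1 and MUC1 rose 14.4-fold (22.4-fold without day 6 replicate 1) and 7.71-fold. SPP1, CTSL, PGR and OXTR did not pass in edgeR, with adjusted p of 0.0784, 0.170, 0.152 and 0.731; that of PGR was 0.0250 without day 19 replicate 1. DESeq2 called SPP1 (0.0203).

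Of 9 glucose transporters 4 rose and 1 fell at day 19, of 24 amino acid transporters 8 and 4, and of 29 integrin and adhesion genes 11 and 3. Adjusted over the list alone these were 5 and 1, 9 and 6, and 13 and 3 (camera, adjusted p = 0.108, 0.537 and 0.159, so none of the 3 lists was called). With day 19 represented by its replicate 1 alone, and the spread taken from the other days, the glucose and integrin lists passed at 0.0468 and 0.00285. SLC5A1 had a ratio of 215 (59.1 to 1780) over 2 counts at day 6, SLC2A1 rose 3.96-fold, SLC36A2 12.2-fold, ITGB6 29.6-fold (19.6-fold without day 19 replicate 1) and the secreted immunoglobulin carrier PIGR 54.0-fold (35.5-fold without day 19 replicate 2). Of single genes, the citrate transporter SLC13A5 changed by -5.38 (SE 0.88; -7.13 without day 19 replicate 1), the sodium channel subunit SCNN1A by -5.06 (SE 0.46), the sphingomyelinase SMPD3 by -5.05 (SE 0.44) and ITGA2 by -3.54 (SE 0.34). SLC14A1, PDZK1 and KRT5 changed by -9.15 (SE 1.23), -6.87 (SE 0.52) and -5.43 (SE 0.72), and SLC14A1 had 4 counts over the day 19 libraries. Without day 6 replicate 1 SLC14A1 and KRT5 changed by -7.68 and -4.70, and without day 19 replicate 2 SLC14A1 changed by -10.37. In the cell cycle list 3 of 35 fell and 1 rose, the same counts when adjusted over the list alone (camera, adjusted p = 0.107; 0.000162 without day 6 replicate 2 and 0.0387 without day 19 replicate 2); the riser was CCNB2 at 5.77-fold, a B-type cyclin as is CCNB1. TIMP1, an inhibitor of matrix proteases, rose 3.03-fold.

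Of 13 mitochondrial genes 7 fell, also 7 when adjusted over the list alone, with a median of -1.20 (camera, adjusted p = 0.000217; adjusted p = 0.701 with an estimated correlation); ND4L changed by -2.84 (SE 0.21) and ND5 by -2.21 (SE 0.25). Of 52 ribosomal protein genes 2 rose, with a median of 0.53 (camera, adjusted p = 0.0121; adjusted p = 0.855 with an estimated correlation). None did in edgeR when adjusted over the list alone, against 15 at an unadjusted p under 0.05 over all genes and 10 by DESeq2. This call was lost without day 6 replicate 1 (0.0696) and without day 19 replicate 2 (0.384) or 3 (0.181), and the list lay lower with day 19 represented by its replicate 1 alone (1.19e-07). Smooth muscle had 2 higher of 21, 1 when adjusted over the list alone (camera, adjusted p = 0.264; 0.00996 without day 6 replicate 2), and testis germ cell 1 lower of 5, or 1 higher and 3 lower when adjusted over the list alone (camera, adjusted p = 0.537). The lists not named for this comparison were not called, at camera adjusted p of 0.291 to 0.913. Among them ciliated epithelium passed without day 6 replicate 3 (0.0348). Camera tests for a shared direction, and some of these lists had members called both ways. Of 21 prostaglandin genes 7 rose and 4 fell, of 32 junction genes 8 and 7, and of 29 implantation regulators 5 and 7. Epithelium had 6 higher and 5 lower of 25, and gland 4 and 3 of 10. Adjusted over the list alone these were 9 and 5, 9 and 9, 7 and 9, 7 and 6, and 4 and 5. Endothelium had 3 lower of 21, or 2 when adjusted over the list alone. Over all genes tested 22.9% were called.

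**Figure D3:**
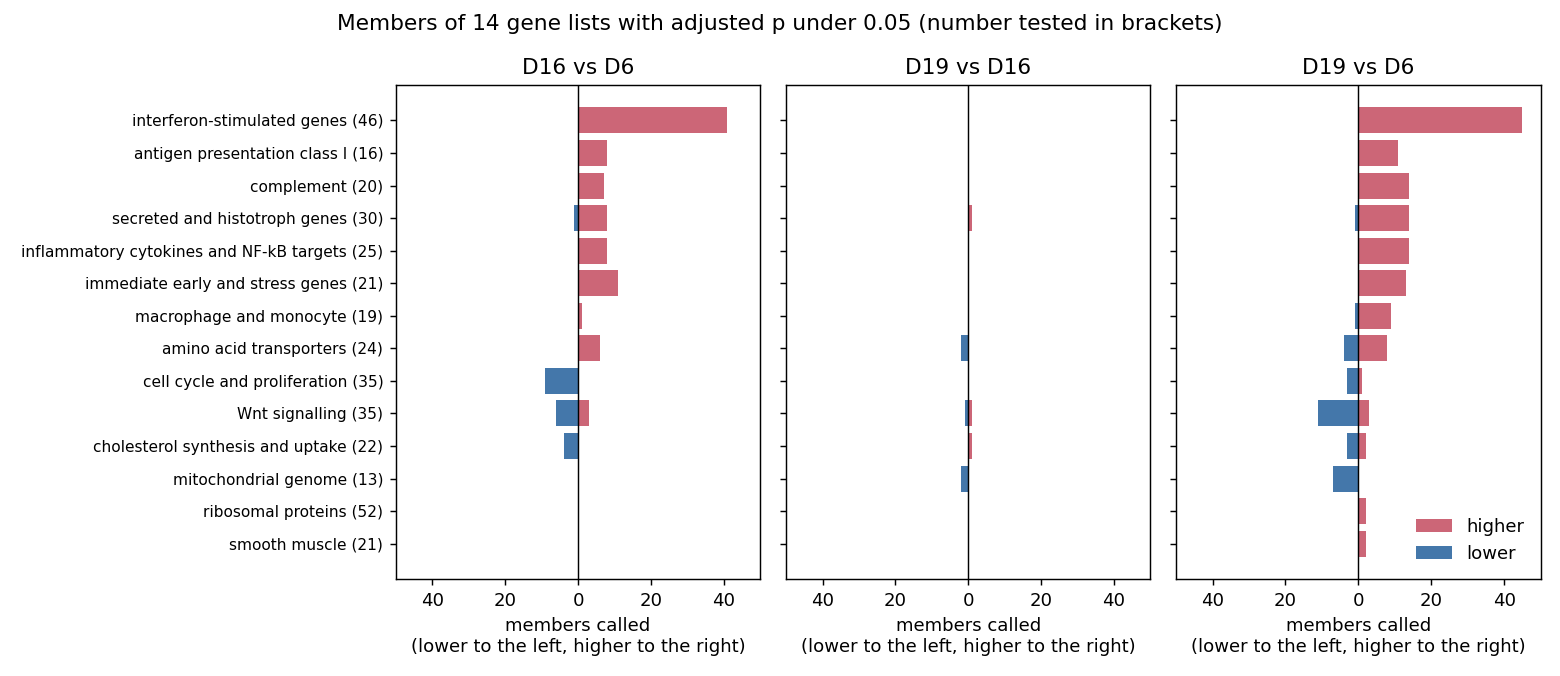
Number of members of 14 gene lists (vertical axis, number tested in brackets) with an edgeR adjusted p under 0.05, drawn to the right where higher and to the left where lower, for each of the 3 comparisons. The interferon-stimulated list had 41 of 46 members higher at day 16 and 45 at day 19 against day 6, and 0 for day 19 against day 16.

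Calls were then compared across days. Of the genes called against day 6, 692 were higher and 497 lower at both later days, and 0 were called in opposite directions. Independent lists of these sizes would share 105 and 61.1. The comparisons share the day 6 libraries: with unchanged groups against them, 20 simulations gave 0.1 shared calls on average (0 to 1). These simulations called only 0.2 genes on average (0 to 1) for day 16 against day 6. Their shared count could therefore hardly rise, and it does not measure the effect of the shared controls. The log2 fold changes of all genes correlated at 0.803 (0.498 simulated) and their covariance was 1.09 (0.095 simulated), a difference of 0.995; genes are not independent replicates. With 3 day 6 libraries the controls could not be split into parts of at least 2 libraries each, so part of the excess may come from the shared controls. The 1189 shared calls were 701, 676 and 576 without day 6 replicates 1, 2 and 3, 687 and 676 without day 16 replicates 1 and 2, and 2277 without day 19 replicate 1.

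Of the 1427 genes called at day 16, 47 were also called between days 16 and 19: 22 went further the same way (7 higher and 15 lower) and 25 turned back (18 first higher, 7 first lower). SLC7A9 was among the 18, rising at day 16 and falling by day 19, and LGALS15 and MX1 were not called a second time. The covariance of the earlier and later changes was -0.037, against -0.096 in simulations of unchanged groups, which share the day 16 libraries. This count was 0 to 3 when any 1 of the libraries other than day 19 replicate 1 was left out (3, 1 and 0 for day 6 replicates 1, 2 and 3, 0, 3 and 0 for day 16 replicates 1, 2 and 3, 1 and 2 for day 19 replicates 2 and 3), and 1588 without day 19 replicate 1; DESeq2 gave 388.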

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

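The fits with day 19 represented by its replicate 1 alone and with the long-minus-short index as a covariate were chosen after the results were seen; the other settings were planned. For day 16 against day 6 the 1427 calls became 2238 with DESeq2, 3811 with voom, 3092 with only those days, 3391 with the index, and 664 to 3345 without 1 library. For day 19 against day 16 the 193 calls became 1681 with DESeq2, 7354 with voom, 429 with the index and 0 to 7331 without 1 library. Of the 429 calls with the index, 127 were among the 193 in the same direction. For these days edgeR called 0 with only their libraries (2726 at an unadjusted p under 0.05). For day 19 against day 6 the 3684 calls became 9433 with voom, 2357 with only those days and 1928 to 8891 without 1 library. With the index 4074 genes were called there, of which 2661 were among the 3684 in the same direction. The F test's 3156 became 5011 with DESeq2, 10629 with voom and 1416 to 9703 without 1 library. The 1189 shared calls ranged from 576 to 2277 and the 47 repeated calls from 0 to 1588 without 1 library, and DESeq2 gave 388 of the latter. The cause was not tested; voom gave day 19 replicate 1 a quality weight of 0.091. Other scalings, filters and a fit without robust estimation, where run, kept these counts within 1.5 times.

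Same-numbered samples did not deviate together (correlations -0.164 to 0.153), so the numbers were taken as names. With the number as a replicate block, edgeR called 1100 genes for day 16 against day 6, 0 for day 19 against day 16 (3572 unadjusted; DESeq2 without the block 1681), 2899 for day 19 against day 6 and 2201 in the F test. Shared calls were 933 and repeated calls 0 with the block. Among named genes the block ended the call of ESR1 at day 16 (0.0556) and of the 25 called between days 16 and 19, and among lists that of class II antigen presentation at day 19 against day 6 (0.056).

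Lists called numbered 15, 9 and 11, and 0 in each comparison with an estimated correlation; without 1 library they ranged from 14 to 21, 1 to 14 and 9 to 12. Directions turned as follows, given as adjusted p, and the cause was not tested. Without the low-count filter these were implantation regulators (0.983) and testis germ cell (0.805) at day 16 against day 6, and testis germ cell between days 16 and 19 (0.787). With day 19 replicate 1 alone against day 16 these were steroid receptors (0.688), amino acid transporters (0.675), integrins (0.467), Wnt (0.800), implantation regulators (0.912), immediate early (0.418), ribosomal proteins (2.58e-15) and ciliated epithelium (0.634). Against day 6 these were junctions (0.977), matrix (0.976), implantation regulators (0.558), cholesterol (0.967), ribosomal proteins (1.19e-07), epithelium (0.453), endometrial gland (0.977) and trophoblast (0.977).

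Other turns came from leaving out 1 library, and the range over all 9 such fits is given. At day 16 against day 6 these were ribosomal proteins (0.245 to 0.923), smooth muscle (0.00203 to 0.992), implantation regulators (0.672 to 0.983), endothelium (0.309 to 0.983) and testis germ cell (0.591 to 0.966). Between days 16 and 19 these were T and NK cells (0.119 to 0.709), immediate early (0.388 to 0.940), matrix (0.0190 to 0.874) and epithelium (0.0165 to 0.657). At day 19 against day 6 these were ciliated epithelium (0.0348 to 0.901), smooth muscle (0.00996 to 0.753), trophoblast (0.640 to 0.931), amino acid transporters (0.374 to 0.901), angiogenesis (0.413 to 0.906), endometrial gland (0.808 to 0.989) and stromal fibroblast (0.702 to 0.931). Log2 fold changes of uncalled genes that turned were OXTR at day 16 (-1.95 to 0.39), between days 16 and 19 (-0.15 to 2.39) and at day 19 against day 6 (-0.50 to 1.17), and between days 16 and 19 RSAD2 (-1.52 to 0.02), PGR (-0.59 to 0.037), LGALS15 (-0.076 to 1.17) and CTSL (-0.60 to 0.54). Of called named genes, 45 of 46, 0 of 25 and 52 of 54 kept their call in all 9 fits.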

Other observations

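The tests of the day 19 libraries and of conceptus transcripts, and the gene families in the next paragraph, were chosen after results were seen; the counts over other splits of the samples were planned.

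Some enzymes of serine synthesis and one-carbon metabolism, which supply building blocks for nucleotides and methylation, fell. At day 16, 5 of 18 fell, with log2 fold changes of -4.59 (SE 0.37) for PSAT1, -3.57 (SE 0.30) for PHGDH, -2.37 (SE 0.21) for MTHFD2 and -1.54 (SE 0.23) for PSPH among them (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p from 0.000194 for PSAT1 to 0.00296 for PSPH). At day 19, 7 fell against day 6. Camera gave adjusted p of 6.89e-05 and 0.00364 over 24 tests of 8 families, and 0.071 and 0.146 with an estimated correlation. The lowest p of the 8 families was that of proteasome subunits, of which 2 of 41 rose between days 16 and 19 and 20 against day 6 (camera, adjusted p = 2.69e-11 and 1.60e-07; 0.377 and 0.534 with an estimated correlation). At day 16 that family had 5 higher (0.604). Its median log2 fold change was 0.698 between days 16 and 19 and 0.655 against day 6. Genes with short messengers had centred medians of 0.826 and 0.659 in 2 of the day 19 libraries and -0.396 in the other. Whether the proteasome rise rests on those 2 libraries, or on the transcript lengths they captured, was not tested and stays open. Between days 16 and 19 camera also called glycolytic enzymes higher (0.00215), keratins higher (0.0315) and solute carriers lower (0.0346), at 0.534, 0.534 and 0.313 with an estimated correlation. TRIM and HOX genes were not called, and the families were not tested again without single libraries. PSAT1 was already among the largest decreases when its family was chosen, so each family was also tested without the genes the report's rule had named. The serine family then had 0.000821 at day 16 and 0.0276 at day 19 against day 6, and proteasome subunits 1.31e-10 for day 19 against day 16 and 3.57e-06 against day 6. Between days 16 and 19 glycolytic enzymes had 0.0291, and keratins (0.153) and solute carriers (0.0808) were no longer called. No family was called by camera with an estimated correlation in this retest, where the lowest adjusted p was 0.139. The retest uses the same data and the same families, so it does not undo their choice after results were seen. Of 26 chemokines and receptors, 5 rose at day 16 and 10 at day 19 against day 6 (camera, adjusted p = 0.000232 and 0.000189; 0.147 each with an estimated correlation; 0.0584 and 0.0276 without the genes already named). Among them were CXCL14 at 101-fold and 64.4-fold, CXCL11 at 6.22-fold and 27.7-fold, and CCR7 at 6.75-fold at day 19. CXCL10, CXCL14 and CCL2 also stand in lists of the report.

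Day 19 replicate 1 lay apart from replicates 2 and 3: an index of 75 long-messenger genes minus 223 genes of 6 short-messenger families was 0.75 against -1.81 and -1.58, and 0.33 to 0.56 over the 6 day 6 and day 16 libraries. Replicate 1 differed from the nearer of its fellows by 2.33, against a range of 0.23 over those 6 libraries. All 6 short families were higher in replicates 2 and 3 than in the other 7 libraries, so a difference in the transcript lengths the libraries captured is a candidate explanation. The families were set by gene name and no transcript length was measured, so length itself was not tested. The smooth muscle medians of replicates 1 and 3 differed by 0.024, and those of replicates 1 and 2 by 0.389. Both lay under the limit of 1.77, the range over the 6 day 6 and day 16 libraries. Day 6 replicate 1, at -1.27, widened that range, so the test could hardly find a difference. The list median showed almost none between replicates 1 and 3, and a different share of smooth muscle stays open. The epithelium medians were -0.426 in replicate 1 and 0.708 and 0.112 in replicates 2 and 3, against -0.354 to 0.215 at days 6 and 16. A different share of epithelium or of other cells was not tested. Whether replicate 1 is a day 16 sample with a wrong label cannot be told apart. On 3 axes from day 16 (0) to the other day 19 libraries (1) it lay at 0.135, 0.163 and 0.097. The left-out day 16 library lay lower each time (0.101, 0.074 and 0.041). These axes were set by replicates 2 and 3, whose index departed from the other libraries, so a place near 0 cannot give the day of replicate 1. Its mitochondrial share was 0.64% against 1.94% to 2.11% at day 16. Alone against 2 day 16 libraries, with its spread assumed from the other groups, it called at least 116 genes and a day 16 library 0 to 3; a single library and its length composition keep this open, and a difference between animals at day 19 was not tested.

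Counts of trophoblast Kunitz domain transcripts, which the ruminant conceptus makes, summed over 7 rows to 4, 0 and 1 in the day 6 libraries, 417, 223 and 14 at day 16, and 559, 8260 and 2235 at day 19. Of the rows tested, LOC102177175 rose by 6.94 on the log2 scale at day 16 (SE 1.78, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.04025) and LOC102188515 did not pass (0.201). Against day 6 both rose at day 19, by 10.4 (SE 1.83, adjusted p = 0.00438) and 13.5 (SE 2.13, adjusted p = 0.00479). Neither passed between days 16 and 19 (0.135 and 0.0602). Pregnancy-associated glycoproteins, another conceptus product, had 1, 1 and 3 counts over 65 rows at day 6, 0, 1 and 20 at day 16 and 79, 7 and 3 at day 19, so day 16 replicate 3 had more of them than Kunitz counts. Placental prolactin-related proteins had 42, 0 and 0 counts over 12 rows in the day 19 libraries, and interferon tau had 1 count over all 9 libraries. Conceptus tissue of a single composition in all day 19 samples is unlikely as far as counting error goes. Glycoprotein counts per 100 Kunitz counts were 14.1 (11 to 17.9) in replicate 1 and 0.0847 (0.0341 to 0.175) in replicate 2, and their intervals lay 62.9 times apart. Replicate 3 stood at 0.134 (0.0277 to 0.393). The intervals leave out the spread between samples, and the contrast rests on replicate 1. Its length index (0.745) differed from those of replicates 2 and 3 (-1.805 and -1.582), which were the 2 libraries that departed from the other days. Conceptus tissue of differing composition, or expression in the uterus itself, stays open.

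Other splits of the samples were counted with the same tests. The real splits called 1427, 193 and 3684 genes, each 1 of 10 splits of its 6 samples, and the highest other split called 0, 1 and 0 by edgeR; 10 splits are too few for a share under 0.05. Over 100 drawn splits of the 9 samples, 1 (the real one) gave as many genes in the F test (3156, highest other 8), 1 as many shared calls (1189, highest other 5) and 1 as many repeated calls (47, highest other 0). For the F test, a random assignment of these libraries to days is thus unlikely to give as many genes, if the libraries are independent. The labels do not say that they came from separate animals, so the splits may show only that libraries of a day are alike. The other 2 counts need genes called in 2 comparisons, while the F test called at most 8 in any other split, so they add nothing to it. The 47 became 0 with the replicate block and 0 to 3 when any 1 library other than day 19 replicate 1 was left out. For gene lists, 4, 6 and 7 of 10 splits called at least as many as the real 15, 9 and 11, with up to 18, 16 and 17, so the number of lists called with the preset correlation is not rare; these splits too are too few for a share under 0.05.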
